A study of Homo sapiens with 6 samples.

How the data were processed

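The data were VDR ChIP-seq peaks from RWPE1 cells exposed for 3 h to 1,25(OH)2D at 10 nM or to ethanol as vehicle. Per the labels' protocols, 3 biological replicates per treatment that passed a ChIP-PCR check at the CYP24A1 and GAPDH promoters were pooled, immunoprecipitated again with anti-VDR antibody or, for material pooled from both arms, with IgG, and sequenced as 36 bp single-end reads from fragments of 100 to 300 bp, in 2 lanes per library whose data were pooled. The lanes were technical, so each arm was 1 sample and no p-value measured a spread between cultures. Per the submitters' processing notes, FastQC, Bowtie 1.1.1, MACS2 and the hg19 build were named, with no role or order given.

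The deposited table was 1 list of 7032 peaks merged over both arms, with a gene symbol, an annotated location, the distance to the TSS, a height for each arm, a DR3 call and a TSS overlap call. The heights were used as a signal of unstated scale: the authors' deposited heights took few distinct values (1266 among the 3760 vehicle peaks), and neither the labels nor the file headers said whether they were pileup or enrichment. A height of 0 was read as no peak listed, and no fold was computed against it. The way in which the authors called a DR3, and the rule by which peaks of the arms were merged, are not given in the sources used here. In the list, 3 peaks carried averaged heights or ends. Peak widths ran from 148 to 1192 bp. The list had 0 IgG columns, so IgG signal was not analysed here. No genome was used, so motifs were not searched in sequence and the authors' DR3 and location calls were taken in place of the planned motif search and random placements.

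Peaks were classed by their heights as listed in both arms, 1,25(OH)2D only or vehicle only. Overlap beyond chance was estimated from 1000 circular shifts of vehicle peaks within their chromosomes. Median heights were compared within an arm by a two-sided permutation test with 100000 resamples. Shares were compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment within each family and an adjusted p threshold of 0.05, and single shares have exact Clopper-Pearson 95% intervals, which cover counting error only. Peaks of one library are not independent replicates. Tall peaks were those with a height of at least 5, with 4 and 6 as alternatives, a limit set after the heights were seen.

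Gene lists, 17 with 519 genes in all, covered known VDR targets, vitamin D metabolism, calcium transport, cell cycle control, oxidative stress defence, apoptosis, NF-kB and inflammation, AP-1 and EGF signalling, TGF-beta and WNT signalling, basal and luminal prostate epithelium, epidermal differentiation, and markers of haematopoietic cells, hepatocytes, neurons, fibroblasts and muscle, and housekeeping genes. A list gene counted as having a peak where the authors named it for one, at any distance, and was tested against the other genes among 20056 protein-coding genes of a gene table of the GRCh38.p14 assembly, which was used for names and for the gene of a cited transcript only. Of 4544 symbols in the list 4297 matched that table, and of 3464 peaks citing a transcript 3419 matched a gene. The named loci were CYP24A1 and GAPDH, the 10 tallest peaks of each class (ranked by 1,25(OH)2D height for shared peaks), up to 15 genes of the lists on VDR targets, vitamin D metabolism and calcium transport, and the 2 tallest members of each other list. Some loci that this rule selects are not reported here.

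The tests were tried on simulated data. The list test found a planted list in 20 of 20 runs and called 1 of 320 null lists over 20056 genes. The planted share was 40% or more against 12%, above that of the VDR targets, and null lists were random genes. Power at the observed shares and the effect of gene spacing were therefore not tried. The DR3 comparison within height bins, on 6859 peaks, returned a median odds ratio of 1.98 for a planted 2 and called 6% of runs without a difference. These values do not show whether differences in height left within a bin affected the odds ratios of the real peaks. Alternatives covered stricter heights, other promoter definitions, other gene distances, gaps of 500 bp between peaks, peaks at transcript ends without a DR3 left out, vehicle heights scaled to those of shared peaks, and the VDR target list without CYP24A1. Computation used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.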

Results

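VDR binding was mapped in RWPE1 cells, an immortalised, non-tumorigenic line of human prostate epithelium, after exposure to the hormonal form of vitamin D, 1,25(OH)2D, which is the ligand of the vitamin D receptor (VDR). Cells at 80% confluence were exposed for 3 h to 1,25(OH)2D at 10 nM or to ethanol as vehicle, and chromatin was immunoprecipitated with an antibody against VDR. Material from 3 biological replicates was pooled per treatment before the sequenced immunoprecipitation, so each arm was 1 library, read in 2 lanes. The vehicle library had 19001312 reads (9001958 and 9999354 per lane) and the 1,25(OH)2D library 19207016 reads (9049349 and 10157667 per lane). An IgG library pooled from both arms had 19345873 reads and carried no value of its own in the peak list used here. With n = 1 library per arm, every p below compares peaks of these libraries and not the conditions, and no spread between replicates could be set beside any value. Positions are on hg19, and the height of a peak is the authors' value, whose unit was not stated.

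CYP24A1, which encodes the enzyme that degrades 1,25(OH)2D, had the tallest 1,25(OH)2D peaks of the list. A distal peak at chromosome 20, 52740082 to 52740566, intergenic and 50.2 kb downstream of the transcription start site (TSS), was listed in both arms, with a height of 13.4 in vehicle and 17.7 in 1,25(OH)2D. The promoter peak at chromosome 20, 52790431 to 52791088, centred 244 bp upstream of the TSS (-244), had a height of 16.5 in 1,25(OH)2D and was listed at 0 in vehicle. It covered the stretch from -252 to -51 that had been assayed by ChIP-PCR. In addition, 3 intergenic peaks were listed in 1,25(OH)2D only, with heights of 7.97 (52743320 to 52743586), 3.55 (52744851 to 52745211) and 5.61 (52757582 to 52757837). Of the 5 peaks, 4 contained a direct repeat with a spacing of 3 bases (DR3), the element bound by VDR with its partner RXR. GAPDH, the negative locus, had 0 peaks. Replicates had been selected for inducible binding at the CYP24A1 promoter and none at GAPDH, so neither result is independent of the selection. This includes the difference between the arms at the CYP24A1 promoter.

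**Figure D1:**
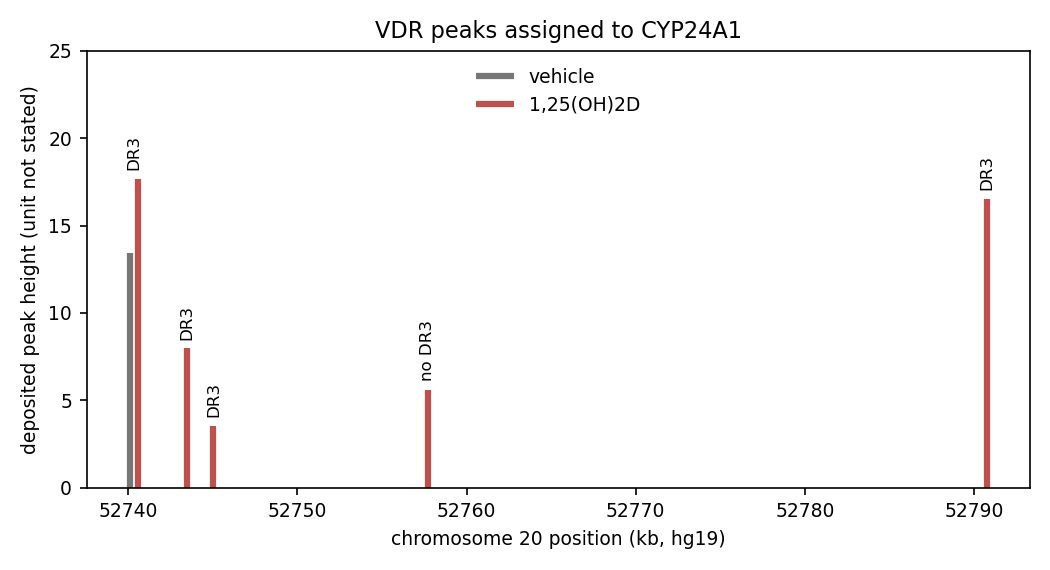
Deposited heights (y axis, unit not stated) of the 5 peaks assigned to CYP24A1 by position on chromosome 20 (x axis, kb, hg19), as one line per arm at the peak centre, with the lines of the peak listed in both arms set apart sideways for legibility. The peak listed in both arms stood at 13.4 in vehicle and 17.7 in 1,25(OH)2D, and the other 4 had no vehicle peak listed.

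The first comparison asked where VDR was found with and without its ligand. FOS, a subunit of the AP-1 transcription factor, was bound in both arms 24.0 kb upstream of its TSS (chromosome 14, 75721070 to 75721489), with heights of 9.69 in vehicle and 13.2 in 1,25(OH)2D. An intron 3 peak of DSCAML1 (chromosome 11, 117467806 to 117468165) had heights of 13.9 in vehicle and 11.2 in 1,25(OH)2D, and a peak 45.2 kb from the TSS of ADAT2 had 12.9 and 12.5 in the same order.

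Such shared sites were few. Of 7032 peaks, 173 (2.46%) were listed in both arms, 3272 in 1,25(OH)2D only and 3587 in vehicle only. The vehicle arm therefore had 3760 peaks, of which 4.60% were shared, and the 1,25(OH)2D arm 3445, of which 5.02% were shared. Vehicle peaks shifted along their chromosomes overlapped a 1,25(OH)2D peak 2.81 times on average over 1000 shifts and at most 8 times (one-sided permutation p = 0.001, the smallest that the shifts could give). Shared peaks were the taller ones in each arm. Their median height in vehicle was 4.22 against 3.15 for vehicle-only peaks, and in 1,25(OH)2D it was 5.18 against 3.15 for peaks of that arm alone (two-sided permutation p = 1e-05 for each, the smallest that 100000 resamples could give). Among vehicle peaks under 3.5 in height, 44 of 2991 were shared (1.47%), against 62 of 70 (88.6%) at a height of 5 or more. The corresponding numbers in 1,25(OH)2D were 29 of 2513 (1.15%) and 94 of 206 (45.6%).

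Peaks that were tall in 1,25(OH)2D and listed at 0 in vehicle included, after the CYP24A1 promoter, intron 10 of DOCK1 (14.3, chromosome 10, 128801172 to 128801783, named for FAM196A), an intergenic site named for BCL2L10 and MAPK6 (10.6, chromosome 15, 52370315 to 52370847) and intron 7 of VTI1A (10.2, named for MIR4295). A peak of 8.81 lay in intron 4 of RALA, a Ras-like GTPase (named for LINC00265). These 4 contained a DR3, as did peaks named for MIR4662B (9.63) and DNAJB8-AS1 (8.96). No DR3 was called at LOC101927575 (13.5), SYT8 (8.56) or B2M, the light chain of class I histocompatibility molecules, whose peak of 9.49 lay in the 3' UTR. The tallest vehicle-only peaks were lower, with 6.84 in intron 6 of CTNNBL1, 6.47 in intron 1 of SEPT9 and 5.56 in intron 1 of FAM120A. The other 7 of the 10 tallest, named for LINC01214, LINC01932, LOC400464, UTP20, MIR2110, LINC01192 and NR2F1-AS1, lay between 4.94 and 5.50. Of these 10, the peaks of SEPT9, LINC01932 and LOC400464 contained a DR3.

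At a height of 5 or more there were 206 peaks in 1,25(OH)2D (5.98% of its peaks) and 70 in vehicle (1.86%), an odds ratio of 3.35 (two-sided Fisher's exact p = 3.82e-20). Shared peaks counted in both arms, and 46 of them were tall in both. The groups of this test, and of its repeat after scaling below, were therefore not independent. Peaks of this height listed in one arm only numbered 112 in 1,25(OH)2D and 8 in vehicle, a ratio of 14. The ratio depended on the height required, which was set after the heights were seen, and was 2.70 at a height of at least 4 (310 against 115) and 24.5 at a height of at least 6 (49 against 2). Heights in the arms came from separate libraries, and shared peaks were themselves higher in 1,25(OH)2D, in 123 of 173 cases, with a median ratio of 1.18 (interquartile range 0.928 to 1.44). After vehicle heights were multiplied by that median ratio, a setting chosen after the data were seen, the one-arm peaks numbered 112 and 57, a ratio of 1.96, and the odds ratio fell to 1.61 (Fisher's exact p = 1.75e-05). The factor came from shared peaks alone, while the median height of all listed peaks was 3.15 in vehicle and 3.17 in 1,25(OH)2D. Among shared peaks, 15 were at least 2 times as high in 1,25(OH)2D and 0 were at most 0.5 times as high. Shared peaks with a DR3 had a median log2 ratio 0.15 above those without, a difference that did not pass (two-sided permutation p = 0.2).

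**Figure D2:**
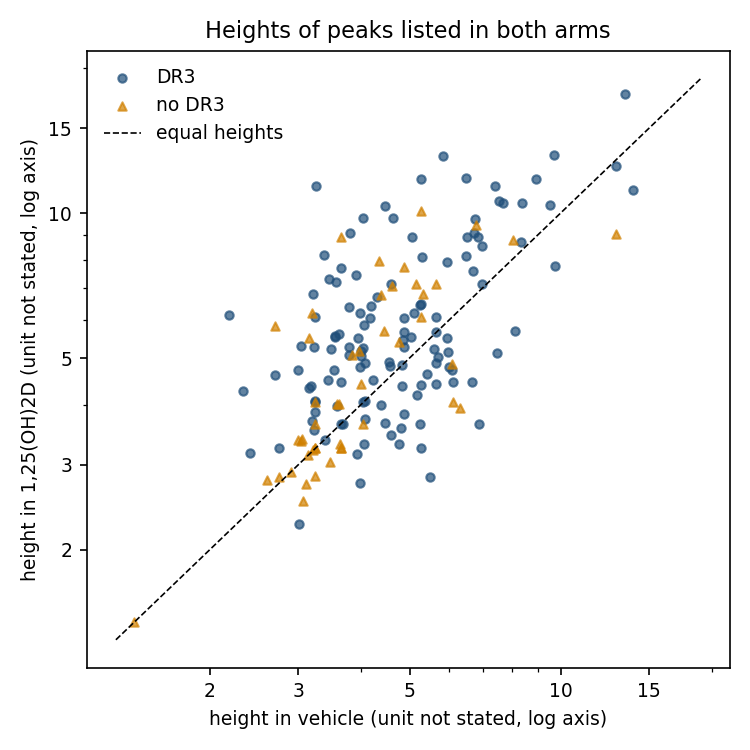
Heights of the 173 peaks listed in both arms, vehicle on the x axis and 1,25(OH)2D on the y axis (both unit not stated, log axes), with one point per peak, circles for peaks with a DR3 and triangles for those without, and a dashed line at equal heights. In all, 123 points lay above the line and 50 below it.

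The next comparison concerned the DR3 element. It was called in 126 of 173 shared peaks (72.8%, exact 95% interval 65.6 to 79.3), including those at FOS, ADAT2 and DSCAML1. Among 1,25(OH)2D-only peaks it was called in 559 of 3272 (17.1%, 15.8 to 18.4), and among vehicle-only peaks in 314 of 3587 (8.75%, 7.85 to 9.73). The odds ratio was 13.0 for shared against 1,25(OH)2D-only peaks (two-sided Fisher's exact p = 2.03e-54, adjusted p = 3.04e-54) and 27.9 for shared against vehicle-only peaks (p = 6.61e-85, adjusted p = 1.98e-84). Between the one-arm classes it was 2.15 in favour of 1,25(OH)2D (Fisher's exact p = 4.41e-25, adjusted p = 4.41e-25). The share rose with height in both arms, from 7.14% of vehicle peaks under 2.5 to 80.0% at 6 or more, and from 9.09% to 76.1% in 1,25(OH)2D. Compared within height bins, a setting added after the data were seen, the odds ratios were 3.39, 15.0 and 1.77 in the same order (permutation p = 1e-05 for each, the smallest possible). Differences in height within a bin were not removed. Shared peaks were also wider, with a median width of 356 bp against 261 bp in 1,25(OH)2D only and 256 bp in vehicle only. A wider peak has more room for a DR3, and width was not adjusted for. At a height of at least 4, also set after the data were seen, the odds ratios were 3.02, 13.9 and 4.62. Among peaks at or above the median height of their arm, classed anew, they were 10.3, 32.1 and 3.12.

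**Figure D3:**
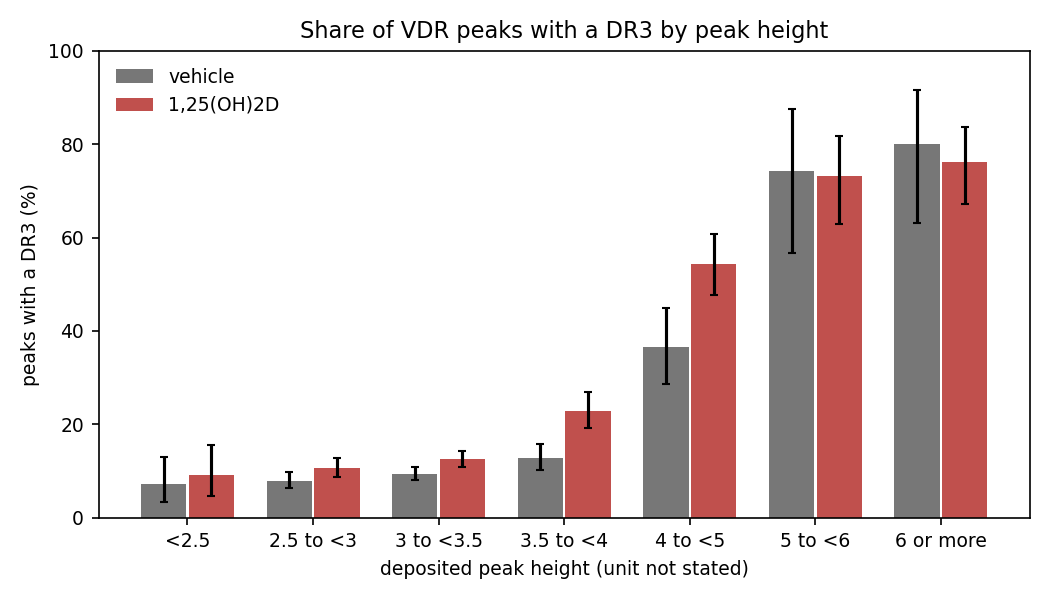
Share of peaks with a DR3 (y axis, %) by deposited peak height (x axis, unit not stated) in vehicle (grey) and 1,25(OH)2D (red), with exact 95% intervals as error bars that cover counting error only. The share was 7.14% and 9.09% in the lowest bin and 80.0% and 76.1% in the highest.

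Promoters were the next question. BGLAP, which encodes osteocalcin, had a shared promoter peak with a DR3 at chromosome 1, 156211201 to 156211678, with heights of 4.38 in vehicle and 3.99 in 1,25(OH)2D. TXNRD1, a thioredoxin reductase, had a shared peak without a DR3 in its 5' UTR (4.03 and 3.65), and TBP, the TATA-binding protein, one with a DR3 in intron 1, 131 bp from the TSS (5.99 and 4.80). Of shared peaks, 20 (11.6%) were annotated to promoters, against 50 (1.53%) of 1,25(OH)2D-only and 31 (0.864%) of vehicle-only peaks. The odds ratio was 8.42 for shared against 1,25(OH)2D-only peaks (Fisher's exact, adjusted p = 1.02e-09 over 16 tests) and 1.78 between the one-arm classes (adjusted p = 0.0429). The latter call was lost when the authors' TSS overlap call replaced the promoter annotation (odds ratio 1.52, Fisher's exact p = 0.0729). For shared against 1,25(OH)2D-only peaks the odds ratio was 15.0 with the TSS overlap call and 4.06 with promoters taken within 5000 bp. The greater width of shared peaks was not adjusted for here either. Most peaks lay elsewhere, with introns holding 42.2%, 43.9% and 43.8% of shared, 1,25(OH)2D-only and vehicle-only peaks and intergenic sequence 37.6%, 50.3% and 51.8%. The intergenic share was lower among shared than among 1,25(OH)2D-only peaks (odds ratio 0.595, Fisher's exact, adjusted p = 0.00704). In the 3' UTR lay 43 1,25(OH)2D-only and 25 vehicle-only peaks (odds ratio 1.90, Fisher's exact, adjusted p = 0.0415), and the 5' UTR held 4 shared against 2 1,25(OH)2D-only peaks (odds ratio 38.7, adjusted p = 0.000681). The other 11 of the 16 tests did not pass.

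Known VDR target genes were named for 1,25(OH)2D peaks more often than other genes. Of 50 such genes, 14 (28%) had a 1,25(OH)2D peak, against 1766 of 20006 other protein-coding genes (8.83%), an odds ratio of 4.02 (two-sided Fisher's exact p = 7.84e-05, adjusted p = 0.00133 over 17 lists). Without CYP24A1, on which replicates were selected, 13 of 49 had a peak (odds ratio 3.73, Fisher's exact, adjusted p = 0.00429). In vehicle 6 of the 50 had a peak (12%, odds ratio 1.29, Fisher's exact, adjusted p = 0.812). Among peaks with a height of at least 4, a setting added after the data were seen, the list passed in both arms, with 4 of 50 genes in vehicle (odds ratio 12.2, Fisher's exact, adjusted p = 0.00813) and 7 of 50 in 1,25(OH)2D (odds ratio 11.7, adjusted p = 9.98e-05). At that height the list had 4 shared and 0 vehicle-only peaks, so the vehicle result rested on peaks listed in both arms. CYP24A1 was among them and was not left out in this setting. The arms were compared directly by peaks, 15 in 1,25(OH)2D only against 4 in vehicle only, and that difference did not pass (odds ratio 4.13, Fisher's exact p = 0.00946, adjusted p = 0.161). Among these genes, FOXO1, a forkhead transcription factor, had a shared DR3 peak in intron 1 (chromosome 13, 41184097 to 41184821, 4.87 in vehicle and 6.06 in 1,25(OH)2D). Listed in 1,25(OH)2D only, with a DR3, were peaks near IGFBP3, which binds insulin-like growth factors (5.69, with the peak at chromosome 7, 45964055 to 45964295), in intron 5 of the cholesterol transporter ABCA1 (5.07), in intron 1 of SLC37A2 (4.35), in intergenic sequence 267 kb from the TSS of CYP26B1, a retinoic acid hydroxylase (3.93), and near the protease inhibitor SERPINB1 (3.56). The peaks of KLK6 (4.06, 5' UTR) and SPP1, which encodes osteopontin (4.04, 3' UTR), had no DR3. Listed in vehicle only, without a DR3, were peaks of GADD45A (3.60 and 3.49), NRIP1 (3.05) and a further one of FOXO1 (2.76).

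No other list passed in 1,25(OH)2D at all heights and distances. Basal prostate epithelium genes came closest, with 8 of 36 (22.2%, odds ratio 2.94, Fisher's exact p = 0.0121, adjusted p = 0.102). They passed within 100000 bp of a TSS (8 of 36, odds ratio 3.79, Fisher's exact, adjusted p = 0.0258) but not at the next shorter distance tried (3 of 36, odds ratio 1.59, adjusted p = 0.589) or within 10000 bp (2 of 36, adjusted p = 0.392). They included ELF3 (6.41, with a DR3) and GRHL2, both epithelial transcription factors. The GRHL2 peak of 5.68 in 1,25(OH)2D only was intergenic, while a vehicle-only peak of 4.33 lay in its 5' UTR, 290 bp from the TSS, and neither had a DR3. Genes of AP-1, MAPK and EGF signalling had 7 of 33 (odds ratio 2.77, Fisher's exact, adjusted p = 0.133), and passed among peaks at or above the median height (odds ratio 5.10, adjusted p = 0.00929) but not at a height of at least 4 (3 of 33, adjusted p = 0.0783) or at the 3 distance limits tried (adjusted p from 0.0657 to 0.392). They included FOS and SPRY2, a feedback inhibitor of receptor tyrosine kinases, whose shared 3' UTR peak had heights of 3.55 and 5.52. For vitamin D metabolism 4 of 20 genes had a peak (Fisher's exact, adjusted p = 0.405), for calcium transport 5 of 31 (0.407), for cell cycle control 4 of 42 (0.954), for oxidative stress defence 3 of 37 (1), for apoptosis 1 of 35 (0.621), for NF-kB, inflammation and prostaglandins 6 of 41 (0.407) and for TGF-beta, WNT and mesenchymal transition 4 of 47 (1). These groups held CDKN2B, a cyclin-dependent kinase inhibitor (5.25, with a DR3), GSTP1 (4.06, none), DAPK1 (3.53, with a DR3), NFKBIA, the inhibitor of NF-kB (4.48, exon 5, with a DR3), and ID3, a partner-blocking helix-loop-helix protein with a shared 3' UTR peak of 6.79 and 9.44 and no DR3. Vehicle-only peaks in these groups included SESN1 (4.33), PLK2 (3.81), XIAP (3.25) and CDKN2B (3.08), without a DR3, and DAPK1 (2.94), with one.

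Lists of other cell types did not pass either. Luminal and androgen-regulated genes had 3 of 19 in 1,25(OH)2D (Fisher's exact, adjusted p = 0.444), haematopoietic cells 2 of 25 (1), hepatocytes 3 of 23 (0.641), neurons 4 of 23 (0.407), fibroblasts and muscle 3 of 21 (0.641), housekeeping genes 2 of 20 (0.911) and epidermal differentiation 0 of 27 (0.407). Peaks at FGG (5.77, transcript end), FGB (4.84, 3' UTR) and COL1A2 (4.47, 3' UTR) were listed in 1,25(OH)2D only and had no DR3. In vehicle no list passed at all heights, the VDR targets at a height of at least 4 being the exception given above, and the lowest adjusted p was 0.310 for neurons, with 6 of 23 genes (odds ratio 3.35, Fisher's exact p = 0.0182). The other vehicle counts were 4 of 20 for vitamin D metabolism, 3 of 31 for calcium transport, 7 of 42 for cell cycle control, 3 of 37 for oxidative stress, 3 of 35 for apoptosis, 4 of 41 for NF-kB, 5 of 33 for AP-1 and EGF signalling, 7 of 47 for TGF-beta and WNT, 4 of 36 for basal and 3 of 19 for luminal genes. They were 0 of 27 for epidermal, 2 of 25 for haematopoietic, 3 of 23 for hepatocyte, 4 of 21 for fibroblast and muscle and 1 of 20 for housekeeping genes.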

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

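The comparison of tall peaks was chosen after the data were seen, as were the alternatives on heights of at least 4, 5 or 6. The same holds for those on the TSS overlap call, height bins, scaled vehicle heights, averaged heights, transcript ends and the cited transcript. It also holds for the middle of the limits on gene distance and the list without CYP24A1. Chosen before the data were examined were the groups, the gene lists, the list test, the height comparison within an arm and the remaining alternatives. Comparisons of DR3 calls and locations between classes, of height ratios by DR3 and of list peaks between arms were not planned. The plan had set DR3 sites against flanking windows and locations against random placements. Overlap had been planned with shuffled peaks of separate lists, which the circular shifts replaced. Of 66 alternatives over 16 results, 56 kept the direction and the side of the threshold or, for counts, stayed close to the main count. A further 9 moved a count and 1 lost its call. Among the 56, leaving out unplaced contigs and chrM could change nothing, because the list had no such peaks. Peak counts depended on the height required: 1973 vehicle and 1723 1,25(OH)2D peaks lay at or above the median height of their arm, 215 and 438 at a height of at least 4, and 70 and 206 at a height of at least 5, by construction. The promoter odds ratio between the one-arm classes was 1.52 with the TSS overlap call (Fisher's exact p = 0.0729), and the cause was not tested. In vehicle 1 list, known VDR targets, passed at a height of at least 4, through shared peaks (odds ratio 12.2, against 11.7 in 1,25(OH)2D). In 1,25(OH)2D 2 lists passed within 100000 bp of a TSS (basal epithelium besides VDR targets) and 2 at or above the median height (AP-1 and EGF signalling besides VDR targets), causes not tested. The odds ratio of tall peaks, 3.35, fell to 1.61 with scaled vehicle heights, still past the threshold. No paired analysis was possible because the shared lane numbers mark technical lanes and the list holds no value per lane, which also ruled out leaving out a lane. Also not run were motif mismatches, windows, flanks and G+C controls (no genome), q-value and fold limits (not in the list used here), reciprocal overlap and centre distance (the list was already merged), and matching on gene spacing and random placements (no annotation of the build). With 19001312 and 19207016 reads per library, 1.47% of vehicle peaks under a height of 3.5 were shared.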

Other observations

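The tests in this part on shared peaks by height, tall peaks, DNA copies and transcript ends of expressed genes were chosen after the result was seen. The loci named here as groups, such as PMEPA1 and AREG, were also chosen after their values were seen.

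PMEPA1, an inhibitor of TGF-beta signalling, had 3 peaks with a DR3 listed in 1,25(OH)2D only. They lay in intron 1 (chromosome 20, 56273273 to 56273551, height 5.20, and 56268087 to 56268691, height 3.55) and in intergenic sequence upstream (56347703 to 56347971, height 6.92). A further PMEPA1 peak, without a DR3, was listed in vehicle only (height 3.00). AREG, which encodes the EGF receptor ligand amphiregulin, also had 3, with heights of 3.15, 3.96 and 3.81, besides peaks without a DR3 in 1,25(OH)2D only (2.92) and in vehicle only (2.81). Further genes with at least 3 such 1,25(OH)2D peaks, shared ones counted, included CYP24A1 (4) and, with 3 each, ADGRL2 and MIR2278. A hypothesis was that DR3 peaks may gather at single genes. The count of such genes was 6, compared with a mean of 3.48 and a highest value of 8 when DR3 calls were permuted 1000 times within height bins (one-sided permutation p = 0.11), so the hypothesis that DR3 peaks gather at single genes did not pass.

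Peaks without a DR3 lay at the 3' ends of SFTPA2 (8.04) and SFTPB (6.47), which encode lung surfactant proteins, of B2M (9.49), the fibrinogen genes FGG (5.77) and FGB (4.84), HLA-B (4.88), HLA-DRA (4.57), COL1A2 (4.47) and SPP1 (4.04), each in 1,25(OH)2D only, among 15 such peaks of height 4 or more, with exons counted as transcript ends throughout, that also included UCA1 (5.26), ARHGEF37 (4.32), MAL2 (4.28), HSPG2 (4.06), ZNF451 (4.03) and IPO8 (4.01). If cDNA of another tissue in the 1,25(OH)2D library were the source, at least 3 of 35 further abundant lung, liver, stromal and immune genes were predicted, before they were looked up, to have such a peak. The count was 0 in either arm, SFTPC and SFTPA1 included, so this prediction failed. For these 35 genes that argues against cDNA of another tissue. The 35 left out the genes that had formed the pattern, which favoured a low count, so the test cannot exclude that source. In addition, 0 of 35 allows a share of up to 10.0%, a limit applied only after the count was seen. By the criterion first set, the explanation would have been rejected. Transcript ends of genes the cells express being pulled down in both arms could also give such peaks. At a height of 4 or more without a DR3, the transcript-end share was 15 of 132 peaks (11.4%) in 1,25(OH)2D only. It was 5 of 89 (5.62%) in vehicle only, at MMS22L, EPHA3, FHIP2B, FSTL5 and EPC1 (odds ratio 2.15, Fisher's exact p = 0.160). ID3 had such a peak in both arms. Of the vehicle-only peaks, those of MMS22L, FSTL5 and EPC1 lay in internal exons and not at a 3' end. The same held for HSPG2 and IPO8 in 1,25(OH)2D only. The comparison was not repeated without exons, so this odds ratio cannot decide whether peaks at 3' ends differed between the arms. Besides those in internal exons, the vehicle-only peaks were at EPHA3 and FHIP2B. Regardless of height and DR3, 43 1,25(OH)2D-only and 25 vehicle-only peaks lay in the 3' UTR (odds ratio 1.90, Fisher's exact, adjusted p = 0.0415). At annotated transcript termination sites the numbers were 28 and 31 (odds ratio 0.990). Counted at any height and with or without a DR3, 5 of 44 hepatocyte and fibroblast genes (FGG, FGB, COL1A2, LUM and COL3A1) had a transcript-end peak in 1,25(OH)2D only, against 1 of 20 housekeeping genes, and 0 and 0 in vehicle only (Fisher's exact p = 0.656, a test likewise added after the counts were seen). The 5 against 1 met the criterion first set against this explanation, at least 2 times as many, and it was left open only through that added test. However, FGG, FGB, COL1A2 and the housekeeping gene, B2M, were among the peaks that had formed the pattern. Neither these counts nor the added test can therefore decide on the explanation.

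Few peaks lay on chromosome 8 below 40 Mb (14, against 363 on the rest of the chromosome) and on chromosome 18 above 20 Mb (30 against 44). Among vehicle-only peaks without a DR3, the density ratio of segment to rest was 0.183 on chromosome 8 and 0.272 on chromosome 18, with 0.536 as the higher of the upper 95% limits. Fewer DNA copies of these segments or fewer VDR sites with a DR3 could each be proposed, but the segments were picked for few peaks of any kind, which by itself held that ratio to at most 0.257 and 0.480, so it tested neither and both stay open. Copy number, mappability and base composition were not measured here. Over 23 chromosomes the densities of vehicle-only and 1,25(OH)2D-only peaks went together (Pearson's r = 0.927, Spearman's rho = 0.812, permutation p = 0.0001 for both, the smallest possible, adjusted p = 0.0002 over 2 relations, and r = 0.880 without the 2 chromosomes farthest from the median). Vehicle-only and DR3-containing 1,25(OH)2D densities gave r = 0.255 (permutation p = 0.24) and rho = 0.118 (p = 0.59). The difference between these correlations was not tested. The DR3 densities rested on fewer peaks, 685 against 3587 vehicle-only and 3272 1,25(OH)2D-only ones.

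Few peaks were listed in both arms. Peaks near the calling threshold being found in one arm by chance may account for much of this, since the shared share of vehicle peaks was 60.2 times as high at a height of 5 or more as under 3.5. Ligand-dependent sites could add to it, since one-arm peaks of height 5 or more were 14 times as many in 1,25(OH)2D as in vehicle, although the ratio was 2.70 at 4 or more and 24.5 at 6 or more. A general gain in peak height in the 1,25(OH)2D library was not excluded, because the ratio was 1.96 after scaling, between the limits of 1.5 and 2 set before that value was seen. The scaling applied the median ratio of shared peaks, 1.18, to all vehicle peaks. Over all listed peaks, median heights were 3.15 in vehicle and 3.17 in 1,25(OH)2D, and upper quartiles 3.38 and 3.54. Shared peaks may themselves respond to ligand, so the scaling cannot separate ligand from library. Peaks below the calling threshold are not listed, so the medians cannot decide it either. After that scaling the ratio also lay below the 2 that ligand-dependent sites had been taken to need, so with 1 library per arm the part played by ligand and by library stays open.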
